A study of Homo sapiens with 6 samples.

How the data were processed

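The series measured chromatin contacts with DLO Hi-C, a digestion-ligation-only form of Hi-C in which short linkers are ligated to digested chromatin before proximity ligation. Per the labels' protocols, cells were cross-linked with EGS and formaldehyde, though the title of 1 THP-1 library, not analysed here, names single cross-linking. Linkers of 20 bp were added, and MmeI released fragments of 80 bp for sequencing. The series has 6 libraries of the leukaemia cell lines THP-1 and K562. TAD lists of 3 THP-1 libraries were analysed, 1 library per group: BglII and HindIII, made by DLO Hi-C, and MseI, made by in situ DLO Hi-C. Groups were taken from the sample titles. The other 3 libraries were not analysed here.

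The values are coordinates: the deposited lists hold a chromosome, a start and an end for each topologically associating domain (TAD), with no score, count or contact value. The submitters' processing notes name BWA 0.7.12-r1039, SAMtools 1.2 and the hg19 build, without a role for each. The TAD caller, its settings and the contact resolution are not given in the sources used here. All starts lay on a 40 kb grid, and the 20, 14 and 21 ends off that grid in the BglII, HindIII and MseI lists all equalled GRCh37 chromosome ends. The lists name a chromosome 23, whose coordinates stay within the GRCh37 length of chromosome X, and it was read as X. No list held overlapping TADs. Depth is unknown, since the lists hold no counts. Intervals therefore describe variation between chromosomes or between TADs of these lists, not between cultures.

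A boundary was a TAD edge away from the chromosome ends, and an end and the next start within 40 kb were merged at their midpoint. Boundaries of different lists were called shared within 40 kb, and the share of a pair is the mean of both directions. TADs were called matched at a reciprocal overlap of at least 80%. Pooled boundaries were joined by single linkage within 40 kb, and the widest spanned 160 kb. Distances to a pooled boundary were taken from its midpoint, rounded down to 20 kb. The boundary of a single list can therefore lie further than 40 kb from a gene counted as near. Chance levels came from 1000 circular shifts of a list within each chromosome, between its first and last TAD edge, with seed 20. The exceptions are all protein-coding genes as a background, with 200 shifts, and the alternatives, with 100 or 200. Intervals of 95% came from 1000 resamplings of the 23 chromosomes, except those of the median lengths, which are binomial intervals of the ranks, and the range given for places of the same G+C content, which covers 95% of 1000 random draws of places. For gene content, protein-coding transcription start sites (TSS) of GENCODE on GRCh37 were counted within 40 kb of each boundary. Recognition sites of BglII, HindIII and MseI and the G+C content were counted in 20 kb bins of the GRCh37 sequence. With 1 library per group no test between conditions was made, and no p-value is given.

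The main comparisons, their settings, 7 gene lists and 10 gene families were fixed before the data were examined. Differences between single-direction shares, differences in matched TADs, boundaries inside TADs and the TSS ratio between boundary classes were not among them. From each of the 7 lists the text names the 2 members whose TADs had the highest, and the 2 with the lowest, minimum pairwise overlap (intersection over union) over the 3 lists of TADs. A member outside any TAD in a list counted as 0, and ties were broken by symbol. The text also names the 3 longest and 3 shortest TADs of each library, the 5 longest TADs with identical ends in all 3 lists, and the genes nearest their ends. Some members that this rule takes, and 1 such TAD, are not reported here. Values per chromosome are given for the highest and lowest chromosome. Alternatives were the distance and overlap thresholds, unmerged edges, autosomes only, TADs of at least 200 kb only, leaving out boundaries that face a TAD-free stretch of over 1 Mb, other windows, and all annotated genes.

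The overlap and enrichment code was tested on simulated lists. With 70.1%, 69.8% and 69.1% of 3266 BglII, 3154 HindIII and 3978 MseI boundaries planted as shared, 72.1%, 72.2% and 72.2% were found, against 73.1%, 72.8% and 72.9% computed from the planted share plus chance. A planted TSS excess of 0.452, 0.454 and 0.442 per boundary was found as 0.446, 0.422 and 0.431. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.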

Results

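TAD lists were compared for 3 libraries of THP-1, a human monocytic leukaemia cell line. The libraries differed by the restriction enzyme that cut the chromatin. BglII and HindIII were used in DLO Hi-C, and MseI, a frequent cutter, in the in situ form of the protocol, so enzyme and protocol change together for MseI. In the GRCh37 sequence the recognition sites lay on average 3711 bp apart for BglII, 3416 bp for HindIII and 150 bp for MseI. Each enzyme had 1 library, so no value below has a replicate, and the sequencing depth of the libraries is unknown.

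The MseI library had the most TADs and the shortest. It held 3319 TADs with a median length of 640 kb (95% interval of the median 640 to 640), against 2476 of 880 kb (840 to 880) for BglII and 2442 of 920 kb (880 to 920) for HindIII. The MseI list had more TADs and a lower median length than either other list on 23 of 23 chromosomes. TADs covered 93.1% of the sequenced bases in the BglII list, 93.8% in the HindIII list and 94.9% in the MseI list. TADs under 400 kb made up 21.1% of the MseI list, 10.7% of the BglII list and 9.54% of the HindIII list. Chromosome X had the highest median TAD length in all 3 lists, at 1260 kb for BglII, 1240 kb for HindIII and 880 kb for MseI. The lowest medians were on chromosome 17 for BglII (680 kb), 15 for HindIII (760 kb) and 20 for MseI (520 kb).

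**Figure D1:**
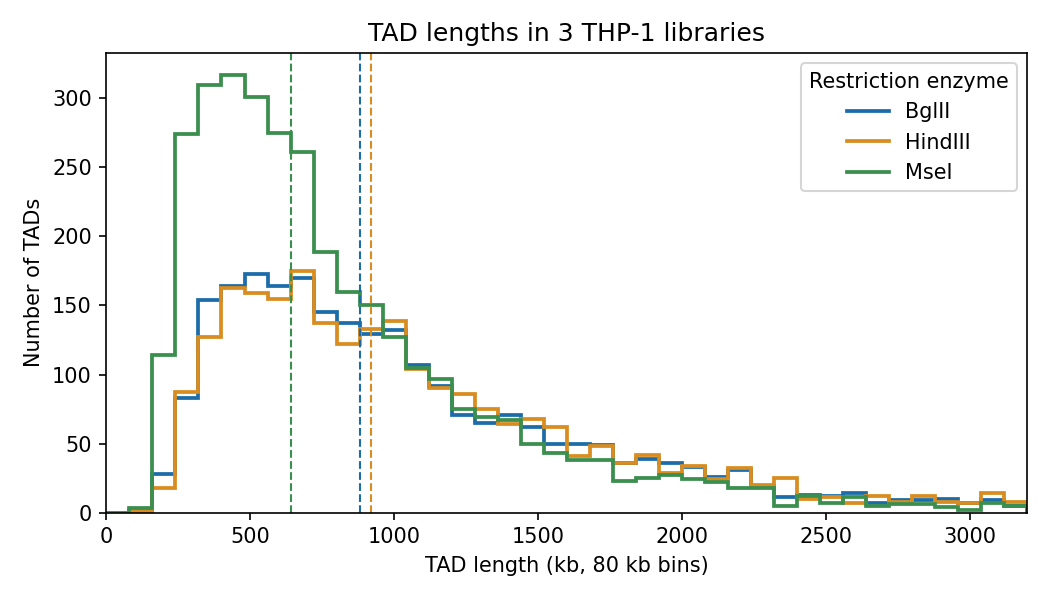
Number of TADs by length in kb (80 kb bins, up to 3200 kb) for the BglII, HindIII and MseI libraries of THP-1, with dashed lines at the medians of 880, 920 and 640 kb. The MseI curve lies above the others at short lengths.

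BglII and HindIII, cut by different enzymes under the same protocol, gave lists of similar size. The median length in the HindIII list was 1.05 times that in the BglII list (95% interval 1 to 1.1, which includes no difference). Of the boundaries, 76.7% were shared (74.5 to 78.7), against a mean of 10.2% and a highest value of 14.6% over 1000 shifts. Matched TADs made up 68.5% (65.3 to 71.5), against a mean of 5.29% over shifts, and 696 TADs had identical ends. Chromosome 19 had the lowest share of shared boundaries, 61.3%, and chromosome 5 the highest, 84.0%. Of the BglII TADs, 82.5% held no HindIII boundary further than 40 kb inside their ends.

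The MseI list was set against each of the other lists to see how far the TADs depend on the enzyme and the in situ protocol. MseI TADs were shorter, with a ratio of medians of 0.727 to BglII (0.696 to 0.773) and 0.696 to HindIII (0.667 to 0.739). BglII and MseI shared 74.7% of boundaries (73.0 to 76.3; shift mean 11.2%, highest 15.6%), and HindIII and MseI 74.8% (73.1 to 76.5; shift mean 11%, highest 15.5%). The directions differed. The MseI list held 82.5% of the BglII boundaries and 83.5% of the HindIII boundaries, while 67% of MseI boundaries were in the BglII list and 66.0% in the HindIII list. BglII boundaries were found in the MseI list more often than in the HindIII list, by 6.83 percentage points (5.16 to 8.72), and HindIII boundaries more often in the MseI than in the BglII list, by 5.80 points (3.82 to 8.05). Shifts of the longer MseI list met 12.3% of the BglII and of the HindIII boundaries, and shifts of the other list met 10.0% and 10.1%. MseI boundaries lay inside 29.6% of BglII TADs and 30.6% of HindIII TADs, whereas 12.1% of MseI TADs held a BglII boundary and 11.2% a HindIII boundary.

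Matched TADs numbered 1684 for BglII and HindIII, 1674 for BglII and MseI and 1628 for HindIII and MseI. Of the BglII TADs, 67.6% were matched in the MseI list and 68% in the HindIII list, a difference of 0.404 points (-2.42 to 2.98). Of the HindIII TADs, 66.7% were matched in the MseI list and 69% in the BglII list, a difference of 2.29 points (-1.01 to 5.10). Both intervals include 0. At an overlap of 50% both differences lay below 0, at -6.91 (-8.73 to -5.21) and -5.20 points (-7.00 to -3.47), with more TADs matched in the MseI list. Of the 3319 MseI TADs, 50.4% were matched in the BglII list and 49.1% in the HindIII list. The means of both directions were therefore lower with MseI, at 59.0% with BglII (57.2 to 60.8) and 57.9% with HindIII (55.2 to 60.8), which is 9.46 points (6.74 to 12) and 10.6 points (7.69 to 13.3) below BglII and HindIII. For shared boundaries the lead of BglII and HindIII was 1.97 points (0.328 to 3.51) over BglII and MseI and 1.95 points (0.287 to 3.40) over HindIII and MseI. At a distance of 20 kb the differences were -1.22 (-2.69 to 0.196, which includes 0) and -2.19 points (-3.65 to -0.915), so the lead over BglII and MseI was lost and that over HindIII and MseI turned. Between BglII and MseI, chromosome 22 shared the fewest boundaries (64.5%) and chromosome 3 the most (81.7%), and between HindIII and MseI chromosome 19 (59.2%) and chromosome 8 (85.2%).

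Pooling the lists gave 4757 boundaries, of which 2252 (47.3%, 44.8 to 49.9) were in all 3 lists. Shifted lists gave 0.631% on average and 0.982% at most. At a distance of 0 kb, 14.1% were in all 3 lists, and BglII and HindIII shared 42.9%, BglII and MseI 44.1% and HindIII and MseI 46.0%. A further 408 were in the BglII and MseI lists, 365 in HindIII and MseI and 184 in BglII and HindIII. Boundaries in 1 list numbered 910 for MseI, 343 for BglII and 295 for HindIII. The 3 lists held 378 TADs with identical ends, 15.3% of the BglII, 15.5% of the HindIII and 11.4% of the MseI TADs.

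**Figure D2:**
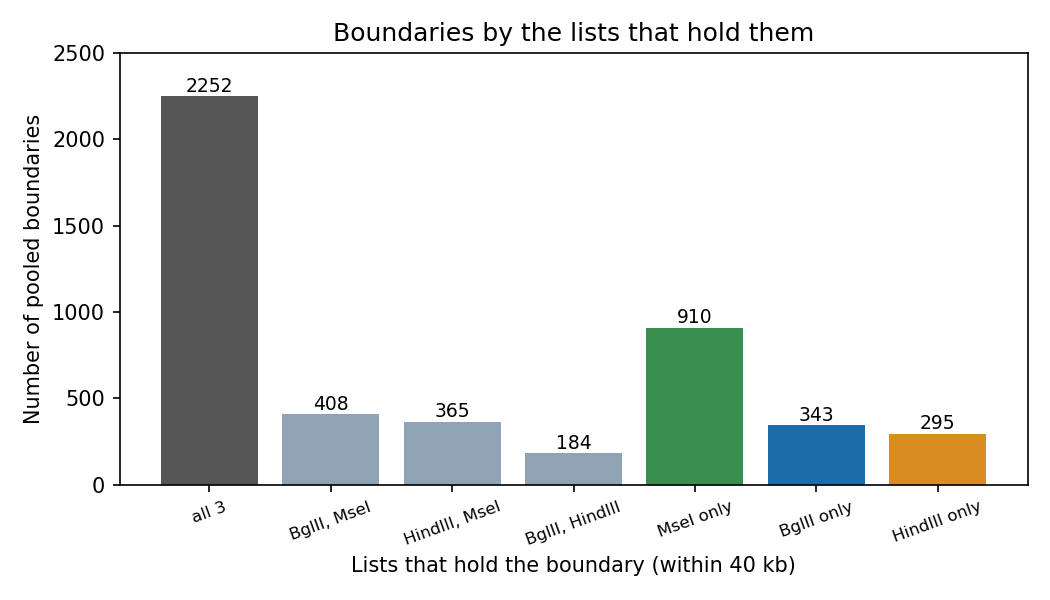
Number of pooled boundaries, joined by single linkage within 40 kb, by the lists that hold them. The bar for all 3 lists reaches 2252, and the bar for MseI only, 910, is the tallest of those for 1 list.

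Protein-coding genes started more often near boundaries than elsewhere, in every list. Within 40 kb there were 1.1 TSS per BglII boundary, 1.09 per HindIII boundary and 1.12 per MseI boundary, against shift means of 0.565, 0.560 and 0.561. The ratios were 1.95 (1.81 to 2.1), 1.94 (1.8 to 2.09) and 1.99 (1.86 to 2.14), and 0 of 1000 shifts came as high for any list. A TSS lay within 40 kb of 59.3%, 57.9% and 58.9% of the boundaries. Boundaries in all 3 lists had a ratio of 2.01 (1.87 to 2.18), those in 2 lists 1.93 (1.73 to 2.13) and those in 1 list 1.89 (1.75 to 2.05). TSS per boundary in all 3 lists over that in 1 list was 1.01 (0.919 to 1.1), so no difference in TSS per boundary was resolved. The surroundings differed. In 40 kb windows 400 kb to either side, boundaries in all 3 lists had 0.319 TSS on both sides, and those in 1 list 0.359 and 0.414. The central 40 kb window held 0.603 TSS per boundary in all 3 lists and 0.592 in 1 list. The step above the surroundings was therefore larger for boundaries in all 3 lists. No interval was computed for this difference, so it was not tested. Boundaries called only with MseI had 1.09 TSS each and a ratio of 1.94 (1.8 to 2.09).

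**Figure D3:**
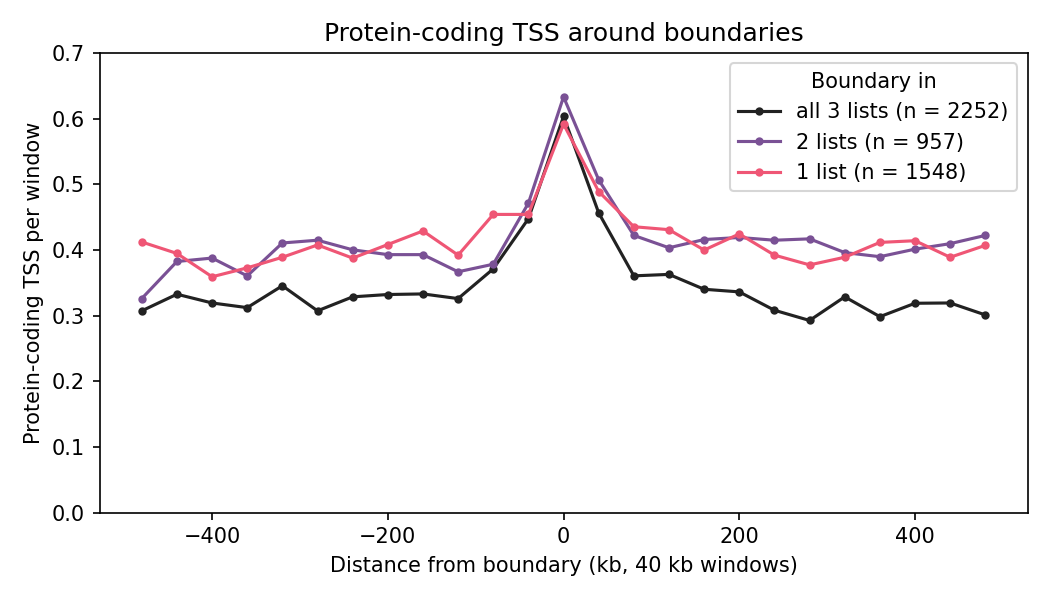
Protein-coding TSS per boundary in 40 kb windows (vertical axis) by distance from the boundary in kb (horizontal axis), for boundaries in all 3 lists (n = 2252), 2 lists (n = 957) and 1 list (n = 1548). The central window holds 0.603, 0.633 and 0.592 TSS per boundary.

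Recognition sites were sparser near boundaries. BglII sites near BglII boundaries had a density of 2.56 per 10 kb, 0.955 times the shift mean, HindIII sites near HindIII boundaries 2.79 per 10 kb (0.955 times) and MseI sites near MseI boundaries 61.3 per 10 kb (0.926 times). None of 1000 shifts gave so low a density in any of these. The G+C content near boundaries was 42.5%, 42.5% and 42.6% in the BglII, HindIII and MseI lists, against shift means of 41.1%, 41.0% and 41.0%.

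HOX genes, which set body position in the embryo, lay near boundaries of all 3 lists more often than in shifted lists. Of 39 HOX genes, 14 (35.9%) had such a boundary within 40 kb of the TSS, against a shift mean of 5.88%, with 9 of 1000 shifts as high. The HOXA and HOXD clusters each held 1 such boundary, and HOXB and HOXC held 0. The 14 genes share these boundaries and are not independent. Of 16 developmental genes with long-range regulation, 4 (25%) did, HOXA9, HOXA13, HOXD13 and MYC, against 6.06%, with 19 of 1000 shifts as high. HOXD13 and MYC were named after their values were seen. Of these 16, 6 are HOX genes, and of the 10 others only MYC was near. HOXA9, HOXA13 and HOXD13 count in both lists, so the 2 lists are not separate results. Neither list was tested against sets of other genes. They were the only 2 of 17 lists above the central 95% of their shifts, where 0.425 would be so if the shifts gave the chance level. Protein-coding genes as a whole also exceeded their shifts, so this number is too low for lists of genes. At a distance of 80 kb neither stayed above it, with 7 of 200 shifts as high for HOX and 26 of 200 for the developmental list. Over all 20090 protein-coding genes the share was 12.3% against 6.15%.

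At the HOXD cluster (chromosome 2, 176957449 to 177055635) all 3 lists had a boundary at 176960000, 2.55 kb from the first TSS and so not resolved from the edge of the cluster on the 40 kb grid. At the HOXA cluster (chromosome 7, 27132612 to 27239710) the boundary lay at 27200000 in the BglII and MseI lists and at 27240000 in the HindIII list, 0.29 kb past the cluster. These lie 1 grid step apart and count as 1 boundary of all 3 lists. HOXB had a boundary at 46720000 on chromosome 17 in the BglII and MseI lists but none inside it in the HindIII list. HOXC had one at 54360000 on chromosome 12 in the MseI list alone, within 40 kb of the start of the cluster. None of the 39 HOX genes lay in a TAD matched over all 3 lists (1 at an overlap of 70%). The clustered protocadherins, adhesion proteins of neurons, differed from them: 52 of 53 lay in matched TADs, divided near 140440000 on chromosome 5 in all 3 lists. At an overlap of 90%, 16 of the 53 did. The cluster overlapped 2 TADs in each list, so this count changes by whole TADs.

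**Figure D4:**
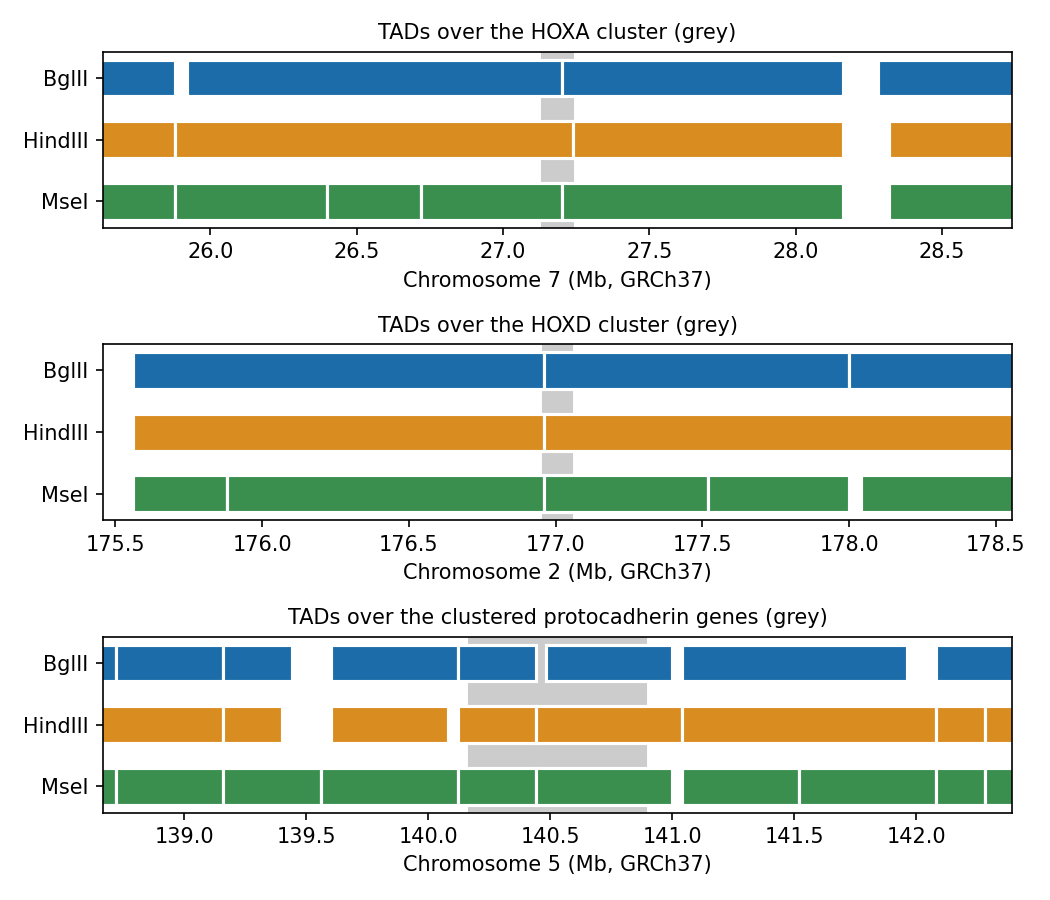
TADs of the BglII, HindIII and MseI libraries (bars, white lines between neighbours) along chromosomes 7, 2 and 5 in Mb of GRCh37, over the HOXA, HOXD and clustered protocadherin genes (grey). All 3 lists have a boundary at 176960000, near the first HOXD gene, and near 140440000, among the protocadherins.

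Of all 20090 protein-coding genes, 6435 (32%) lay in matched TADs. Neighbouring genes of a family can share a TAD, so the counts below are not of independent genes. No chance level was computed for them. Of the other families, 46 of 66 replication-dependent histone genes lay in matched TADs (31 at an overlap of 90%). So did 223 of 515 ZNF genes, which encode zinc finger proteins (130 at 90%). The numbers were 114 of 415 for olfactory receptor genes (81 at 90%) and 27 of 55 for keratin genes (27 at 90%). For the 19 HLA, 7 KIR and 24 SERPINA and SERPINB genes the number was 0, and for the 40 beta-defensin (DEFB) genes 1 (3 at an overlap of 70% and 0 at 90%). A boundary of all 3 lists lay within 40 kb of 15 histone genes (22.7%; central 95% of shifts up to 25.8%), 31 ZNF, 21 olfactory receptor, 6 DEFB, 2 protocadherin and 1 SERPIN genes, and of 0 HLA, keratin and KIR genes. The 12 histone genes within 20 kb and the 18 DEFB genes within 80 kb were above the central 95% of shifts.

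Of 25 monocyte and macrophage genes, 21 lay in a TAD in all 3 lists and 6 in a matched TAD (3 at an overlap of 90%). TLR4, a receptor for bacterial lipopolysaccharide, lay in a TAD of 3080 kb (chromosome 9, 120240001 to 123320000) and TNF, an inflammatory cytokine, in one of 480 kb (chromosome 6, 31480001 to 31960000), both identical in all 3 lists. CD68, a macrophage marker, lay in TADs of 840 kb (BglII) and 1040 kb (HindIII) but in no MseI TAD. Its TSS lay 2.81 kb from an MseI boundary, so this absence is not resolved on the 40 kb grid. ELANE, the neutrophil elastase gene, lay in no HindIII TAD. Counted from the pooled midpoint, a boundary of all 3 lists lay within 40 kb of 3 of the 25 (12%, shift mean 5.94%). These were FCGR1A, S100A9 and TLR8, named after their values were seen. The nearest BglII boundary itself lay 45.8 kb from FCGR1A, and the nearest MseI boundary 50.3 kb from S100A9.

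Of 12 erythroid genes, 2 lay in a matched TAD (1 at an overlap of 90%): GATA1, in TADs of 600, 680 and 560 kb in the BglII, HindIII and MseI lists, and LMO2, in TADs of 680, 720 and 720 kb. KLF1 lay in no HindIII TAD, with its TSS 38.0 kb from the nearest HindIII boundary. Of 12 lymphoid genes, 6 lay in a matched TAD. The TAD of EBF1, a B-cell transcription factor, was identical in all 3 lists (1360 kb), and that of GATA3 had a lowest overlap of 0.978. LCK, a T-cell kinase, lay in a TAD of 1640 kb in the BglII and HindIII lists and of 200 kb in the MseI list, and CD79A lay in no TAD.

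Of 12 housekeeping genes, 2 lay in a matched TAD (1 at an overlap of 90%), among them GUSB (lowest overlap 0.976). HPRT1 lay in no HindIII TAD and RPLP0 in a BglII TAD alone. Their TSS lay 5.8 and 0.962 kb from a HindIII boundary. Their absence from HindIII TADs is therefore not resolved on the 40 kb grid. Of 12 chromatin folding genes, 4 lay in a matched TAD. RAD21, a cohesin subunit, lay in an identical TAD of 2480 kb, and PDS5B started 0.589 kb from a boundary of all 3 lists. SMC3 lay in TADs of 2480 and 2520 kb in the BglII and HindIII lists and of 720 kb in the MseI list, and STAG2 lay in no HindIII TAD. Of the 16 developmental genes 8 lay in a matched TAD. SOX2 (2080 kb) and SOX9 (1920 kb) lay in identical TADs, and HOXA9 and HOXA13, which start between the TAD ends at 27200000 and 27240000, had a lowest overlap of 0.0175. Of 12 leukaemia genes 3 lay in a matched TAD (1 at an overlap of 90%), among them MEIS1 (lowest overlap 0.984) and MLLT1 (0.875). AFF1, a KMT2A fusion partner, lay in a TAD of 2200 kb with BglII and HindIII and of 200 kb with MseI. A boundary of all 3 lists lay within 40 kb of 2 lymphoid genes, EBF1 and RAG1, though the nearest HindIII boundary itself was 53.1 kb from EBF1. The same held for 1 gene each of the erythroid, housekeeping (HPRT1), chromatin folding (PDS5B) and leukaemia (AFF1) lists. RAG1 was named after its value was seen.

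The longest TADs identical in all 3 lists held few genes. On chromosome 4, 27040001 to 30680000 (3640 kb) held 0 protein-coding TSS, with STIM2 and PCDH7 nearest its ends. Others were 58800001 to 62200000 on chromosome 16 (3400 kb, with CDH8), 51480001 to 54800000 on chromosome 7 (3320 kb, between COBL and SEC61G) and the TLR4 domain on chromosome 9, between ASTN2 and CDK5RAP2.

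The 3 longest BglII TADs, the 2 longest HindIII TADs and the longest MseI TAD held boundaries of both other lists. The longest BglII TADs were 91200001 to 99720000 on chromosome X (8520 kb, PCDH11X and PCDH19 nearest its ends), 21200001 to 27280000 on chromosome 9 (6080 kb, IFNA7 and EQTN) and 122960001 to 128640000 on chromosome X (5680 kb, XIAP and SMARCA1). The HindIII list had 2 boundaries and the MseI list 5 inside the chromosome 9 TAD. The longest HindIII TADs were 37480001 to 44480000 on chromosome 9 (7000 kb, POLR1E nearest its start, with 3 BglII and 6 MseI boundaries inside), 54560001 to 59920000 on chromosome 10 (5360 kb, MBL2 and IPMK, with 2 and 2) and 19760001 to 24640000 on chromosome 19 (4880 kb, GMIP and ZNF254), which held 41 protein-coding TSS and 1 BglII boundary and had the same ends in the MseI list. The longest MseI TAD, 120720001 to 142720000 on chromosome 1 (22000 kb), was 96.5% unsequenced bases and had 1 BglII and 2 HindIII boundaries inside, and 80160001 to 84680000 on chromosome 2 (4520 kb, LRRTM1 and SUCLG1, with 1 BglII boundary inside) was also among its longest.

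The shortest TADs measured 120 or 160 kb. Of the BglII TADs 2466 of 2476 measured at least 200 kb, and of the HindIII TADs 2437 of 2442. Other TADs under 200 kb in these lists are therefore not named here. In the BglII list those named are 66440001 to 66560000 on chromosome 9 and, on chromosome 1, 1680001 to 1840000 (CDK11A and CALML6) and 25000001 to 25160000 (SRRM1 and CLIC4). The chromosome 9 TAD was 12.2% unsequenced bases, and its nearest gene, SPATA31A7, lay 930 kb from its start. In the HindIII list they were 175640001 to 175760000 on chromosome 5 (SIMC1 and KIAA1191), 16880001 to 17040000 on chromosome 1 (holding NBPF1) and 110840001 to 111000000 on chromosome 2 (MALL and MTLN). In the MseI list they were 150240001 to 150360000 on chromosome 5 (IRGM and GPX3), 77280001 to 77400000 on chromosome 7 (RSBN1L and TMEM60) and 34520001 to 34640000 on chromosome 17, holding the chemokine genes CCL3L3 and CCL4L2.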

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

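Alternatives numbered 187 for 70 results. Of these, 51 chosen in advance and 89 added after seeing the data were counted as kept. Differences, ratios and enrichments counted as kept when direction and side of the threshold stayed. For genes near a boundary only the side was compared, so a list above the threshold in neither setting counted as kept. The lymphoid list was such a case, with 2 genes at 40 kb and 0 at 20 kb. Shares and median lengths counted as kept when they moved by less than the counting interval. Numbers of TADs and of genes in matched TADs did when they stayed within a set factor of the main value, a looser rule. The added settings are assembly gaps removed before shifting, TADs over 50% unsequenced left out, single-direction and matched-TAD differences and inner boundaries. They also cover TSS at boundaries of all 3 lists and of MseI only, and all gene list settings. Numbers and lengths of TADs, ratios of medians, TSS enrichment and cut site density were kept in all that were run. The size of the TSS ratios for BglII, HindIII and MseI still moved. It was 1.56, 1.57 and 1.54 with all annotated genes and 1.87, 1.86 and 1.91 with assembly gaps removed before shifting. Windows of 80 kb gave 1.70, 1.71 and 1.71, and windows of 20 kb gave 2.12, 2.06 and 2.21. Shares follow the threshold by construction. For BglII and HindIII, BglII and MseI, and HindIII and MseI in this order, shared boundaries were 42.9%, 44.1% and 46.0% at 0 kb, 61.7%, 62.9% and 63.9% at 20 kb, 82.3%, 79.5% and 79.3% at 80 kb, 84.2%, 81.4% and 81.1% at 120 kb, and 80.4%, 78.1% and 77.8% with starts and ends not merged. Matched TADs were 87.0%, 81.7% and 80.7% at an overlap of 50%, 74.7%, 65.3% and 64.0% at 70%, and 59.0%, 49.7% and 49.97% at 90%. Boundaries in all 3 libraries were 14.1% at 0 kb, 32.5% at 20 kb, 53.8% at 80 kb and 56.6% at 120 kb. At an overlap of 50%, TADs matched in the other list minus those matched in MseI reversed, to -6.91 points for BglII and -5.20 for HindIII; the cause was not tested. The lead of BglII and HindIII in shared boundaries changed sign at 20 kb, to -1.22 points against BglII and MseI (-2.69 to 0.196, not resolved from 0) and -2.19 against HindIII and MseI (-3.65 to -0.915); the cause was not tested. At 80 kb from the TAD ends, 9.13% of MseI TADs held a BglII boundary and 8.41% a HindIII boundary. At an overlap of 90%, matched genes were 3 for the monocyte list and 1 each for the erythroid, housekeeping and leukaemia lists. They were 16 for protocadherins, 130 for ZNF and 0 for DEFB, and at 70% 1 for HOX and 3 for DEFB. Among those counted as kept by the set factor were 81 for olfactory receptors and 31 for histones at 90%, and 9 for the monocyte list at 70%. Genes near a boundary of all 3 lists numbered 18 for HOX and 4 for the developmental list at 80 kb, no longer above the central 95% of shifts. Histones at 20 kb (12) and DEFB at 80 kb (18) rose above it; the cause was not tested. No paired analysis was possible because each group has 1 library and the results come from no test between groups. Depth is unknown, so what it limits could not be measured.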

Other observations

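In this section, the tests chosen only after the results were seen are those of the gene classes, of gene density by TAD length and of unsequenced bases. So are those of sites at the start of chromosome X, of genes shared with chromosome Y and of loss of a stretch. Genes of ribosomal proteins lay near boundaries more often than matched genes. Of 84 cytosolic ribosomal protein genes, 28 (33.3%) had a boundary of all 3 lists within 40 kb of the TSS, against a shift mean of 6.03% (ratio 5.53), and of 78 mitochondrial ribosomal protein genes 23 (29.5%, shift mean 6.22%). None of 10000 random sets of protein-coding genes matched on the number of TSS within 500 kb reached either share, and the matched means were both 12%. Proteasome subunit genes (8 of 39, 20.5%) were reached by 902 of 10000 matched sets, and solute carrier genes (36 of 373, 9.65%) by 9688. Among RNA genes, the share was 12.4% of 1455 snoRNA genes (ratio 2.01), 8.80% of 1897 snRNA genes (1.43), 8.69% of 18592 lncRNA genes (1.41) and 7.40% of 3029 miRNA genes (1.22), for which 43 of 1000 shifts came as high.

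Short TADs were gene-rich and long TADs gene-poor. TADs under 400 kb held 12.1 (9.85 to 14.2), 12.4 (10.8 to 14.4) and 12.8 (11.1 to 14.4) protein-coding TSS per Mb in the BglII, HindIII and MseI lists, and TADs over 2 Mb 2.87 (2.15 to 3.74), 3.05 (2.18 to 4.50) and 1.33 (1.04 to 1.69). The G+C content was 44%, 44.1% and 44% in the short TADs and 38.4%, 38.5% and 37.5% in the long ones.

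The MseI list had more and shorter TADs, with 910 boundaries of its own. These lay outside every TAD of both other lists in 7.14% of cases, and inside a TAD of both in 85.7%. The BglII and HindIII TADs covered 93.1% and 93.8% of the sequenced bases, so a low share outside was given in advance. It cannot decide on reach into TAD-free stretches, and shows only that most of these boundaries lay inside TADs of the other lists. MseI sites were slightly less dense at MseI-only boundaries than at boundaries of all 3 lists (ratio 0.965, 0.936 to 0.994). This argues against MseI-only boundaries lying where MseI sites are locally denser. It cannot tell whether the frequent cutting of MseI as a whole gave more TADs, since it compares only places along the genome. The MseI-only boundaries carried 1.09 TSS each, above the central 95% of shifts (up to 0.637), so placement without regard to genes is unlikely. Windows 400 kb to either side were not compared for them, so a gene-rich neighbourhood alone was not tested. For BglII and HindIII sites the ratio of density, MseI-only boundaries over boundaries of all 3 lists, was 0.983 (0.956 to 1.01). The prediction set in advance for sparse sites, an interval wholly under 1, was not met. A slightly lower density stays possible, since the interval reaches below 1. Depth, enzyme and the in situ protocol cannot be separated with 1 library each and remain untested candidate explanations.

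Protein-coding TSS were concentrated at boundaries of all 3 lists. Places of the same G+C content on the same chromosome had fewer, with a ratio of 1.61 (1.51 to 1.71 over random draws), and windows 400 kb to either side had fewer as well, with a ratio of 1.74 (1.66 to 1.85). G+C content alone, or a gene-rich neighbourhood alone, is therefore unlikely to account for it. A link between gene starts and boundaries in these cells may be proposed as a hypothesis, found and tested on the same lists. The design holds no group that tests a biological explanation.

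No list had a TAD in 2 stretches of chromosome X. The stretch from 41760001 to 44920000 had the same ends in all 3 lists and held the TSS of 9 protein-coding genes, among them the monoamine oxidase genes MAOA and MAOB and the histone demethylase gene KDM6A, while the stretch from 1 to 2680000 held 16, among them CSF2RA and IL3RA. In the former, unsequenced bases made up 0%, the lowest site density ratio to chromosome X was 0.981 and 0.633% of sampled 100-base words occurred on chromosome Y, which argues against unsequenced bases, few sites and sequence shared with Y; loss of the stretch from the THP-1 cells could not be tested, since 0 lists with a TAD there is what defined the stretch. In the latter, 93.8% of the genes are annotated on chromosome Y too, consistent with contacts lost to sequence shared with Y, while unsequenced bases (13.4%) and few sites stay open, since the site density ratios to chromosome X were 0.637 for BglII, 0.549 for HindIII and 0.448 for MseI. Both stretches were chosen after they were seen.

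Elsewhere, 3 stretches of at least 500 kb with under 50% unsequenced bases had no TAD in any list: 46360001 to 46880000 on chromosome 10, 82600001 to 83160000 on chromosome 15 and 24800001 to 25360000 on chromosome 21, which holds 0 protein-coding TSS.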
